A study of Mus musculus with 2 samples.

How the data were processed

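Forebrains of mouse embryos (strain B6NCrl, males and females pooled) at 12.5 days were assayed by chromatin immunoprecipitation with an antibody against H3K27ac. Per the labels, replicate 1 was pooled from 120 embryos and replicate 2 from 68, and both are biological replicates of 1 group, so no comparison between groups was possible. The 2 replicates come from separate pools of embryos. Peaks are on the mm10 assembly per the labels.

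Per the file lists deposited with the samples, the authors called each replicate's peaks on its filtered alignments with 1 control file, and the pooled peaks on both replicates with both control files. The replicated peaks were derived from the pooled list and both replicates' lists. Their exact selection rule and the peak caller are not given in the sources used here. Checked on the values, every replicated peak is an identical entry of the pooled list, and the replicated peaks make up 47.5% of that list. The fold enrichment of each peak is the authors' deposited ratio of immunoprecipitated over control signal, and the authors' −log10 p and −log10 q values are those of the peak caller within 1 list, not tests across replicates. These per-peak values are the authors' own and were used only to describe, rank or filter peaks within a list, apart from 1 rank correlation between matched peaks. The lowest −log10 p was 2.00 in the pooled list, so the lists hold many weak peaks: 33.8% of pooled, 68.2% of replicated, 27.3% of replicate 1 and 23.5% of replicate 2 peaks had a −log10 q of at least 5. The lists hold no read counts, so depth is unknown and no precision per peak can be given. Between 10 and 14 peaks per list lay on unplaced scaffolds and were left out.

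Gene models were the 21938 protein-coding genes of the GENCODE M21 annotation on GRCm38, the assembly also called mm10, with 93513 transcription starts. The genome sequence and chromosome lengths were those of GRCm38. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots from matplotlib 3.10.9, all with fixed random seeds.

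Peaks were shared if they overlapped by at least 1 base. Chance was measured with 1000 circular shifts of the peaks along each chromosome, which do not avoid assembly gaps. A peak was placed once, in the order promoter (within 1 kb of a protein-coding start), exon, intron, intergenic. Only protein-coding genes were used for this, so an intergenic peak can lie over a noncoding gene. A gene had a promoter peak if a replicated peak lay within 1 kb of any of its starts. A distal peak lay over 1 kb from every protein-coding start and was assigned to the gene with the nearest start within 100 kb. The sequence nearest to a gene's starts within that limit is its territory, and covered bases are those of replicated peaks in the territory. Domains were peaks stitched over gaps of up to 12.5 kb and ranked by covered bases, since no read coverage was at hand, and the 500 highest were tested through the genes that start inside them or, failing that, nearest to them.

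There were 24 gene lists, fixed before the data were examined, with 368 genes named in advance in 376 list places, all found in the annotation, plus the olfactory receptor genes taken by symbol. Promoter peaks and domains of a list were compared with all other protein-coding genes by two-sided Fisher's exact tests. Distal peaks per gene were compared with 100000 random lists of the same size, drawn with replacement within the same decile of territory length. All were adjusted over the 24 lists by the Benjamini-Hochberg method at a threshold of 0.05. Genes within a list are not independent of each other, and several genes stand in 2 lists (Otx2, Rax, Six6, Lmx1a, Hand2, Hoxa2, Hoxb1 and Hoxb2). The p of the olfactory receptor list for promoter peaks was too small for the software to return and is not given. Telencephalon lists were also tested directly against midbrain and hindbrain genes and against genes of 4 other tissues, with Fisher's exact test and a permutation of gene labels. The genes with a promoter peak in each replicate were compared with exact McNemar tests, over all genes and within each list.

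Each of 17 motifs of 6 or 7 bases was counted on both strands in distal replicated peaks and in equally long intervals 5 kb to the right that overlap no pooled peak. The ratio was ranked among those of all rearrangements of the motif's bases with the same number of CpG, a motif and its reverse complement counting once. Intervals for chromosome X are 95% Poisson intervals and cover counting error only.

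Genes named are, by a rule fixed before the data were examined, those at the 20 domains with the most covered bases, at the 10 peaks of highest fold enrichment and with the 10 highest numbers of distal peaks, up to 4 members of each list with the most covered bases, and the members of a list with or without a promoter peak where these are 5 or fewer. Emx2 and the Hoxa genes were chosen for the map after their values were seen. Alternatives fixed before the data were examined were each replicate's list alone, the pooled list, peaks at or above the median fold enrichment or at −log10 q of at least 5, other overlaps, promoter windows, territory limits, backgrounds, stitching distances, domain numbers and rankings, and other motif controls.

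The tests were run on simulated data. Unrelated lists of 20000 peaks, placed at random along the chromosomes, were called shared in 4.5% of 400 runs. In such lists 50.4% of peaks were found shared where 50% were planted. Real peaks prefer promoters, which these simulated lists do not, so the 4.5% need not hold for real lists. Random lists of 16 genes were called at p of 0.05 in 4.4% of runs for promoter peaks, 4% for distal peaks and 3% for domains. Lists with promoter peaks planted in 90% of their genes were called in 94.0% of runs and lists with 75% planted in 40.0%. Lists with 4 times the distal peaks were called in 71% of runs and lists with 2 times in 25.5%, so smaller differences in distal peaks are often missed at this list size. All 17 motifs planted as 1 copy in 25% of 4000 random sequences ranked at the top of their rearrangements. Weaker enrichment was not simulated, so the power to find small ratios is unknown. Of 17 unplanted motifs 1 reached p of 0.05 by the exact rank test.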

Results

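H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the forebrain of mouse embryos at 12.5 days. The forebrain holds the telencephalon, from which the cortex and basal ganglia arise, and the diencephalon, from which the thalamus and hypothalamus arise. The series had 1 group with 2 biological replicates, pooled from the forebrains of 120 and 68 embryos of both sexes. Replicate 1 had 107627 peaks on the assembled chromosomes, with a median width of 263 bases and 50.1 Mb covered. Replicate 2 had 100269 peaks, with a median width of 259 bases and 45.2 Mb covered. The pooled list held 116507 peaks over 62.2 Mb, and the replicated list, the authors' selection from the pooled list, held 55291 peaks over 47.7 Mb with a median width of 573 bases. The peak lists carry no read counts, so the sequencing depth behind each list is unknown.

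The question the replicate pair can answer is which acetylated regions were found in both pools of embryos. Some promoters of forebrain regulators had high fold enrichments in both lists, although the housekeeping list had the highest median of all lists, 18.6 in replicate 1 and 15.8 in replicate 2. The peak at the start of Nr2f1, a nuclear receptor that patterns the cortex, had a fold enrichment of 55.6 in replicate 1 and 51.8 in replicate 2. The peak at Sox2, a neural stem cell factor, had 53.1 and 39.1, and the peak at Msi1, an RNA-binding protein of neural progenitors, had 50.7 and 45.8. Of the genes of the dorsal telencephalon, ventral telencephalon, neural progenitor and newborn neuron lists, every member carried a promoter peak in each replicate.

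Over all peaks, 48.5% of those of replicate 1 overlapped a peak of replicate 2, and 54.3% of those of replicate 2 overlapped a peak of replicate 1. Circular shifts of one list along the chromosomes gave 3.42% ± 0.202 (SD over 1000 shifts), so the observed share was 14.2 times the chance share (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). With an overlap of at least 50% of both peaks the share of replicate 1 was 29.1%, against 0.629% by chance (permutation test, p = 0.001). The covered bases of the 2 lists had a Jaccard index of 0.447. Sharing followed fold enrichment within each list. In the lowest quartile 24.4% of replicate 1 peaks were shared, and in the highest quartile 93.0% were. The same shares were 30.7% and 95.2% for replicate 2. Across 46706 peaks matched 1 to 1, the fold enrichments of the replicates had a Spearman's rho of 0.724; this is a correlation across peaks, which are not independent replicates.

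**Figure D1:**
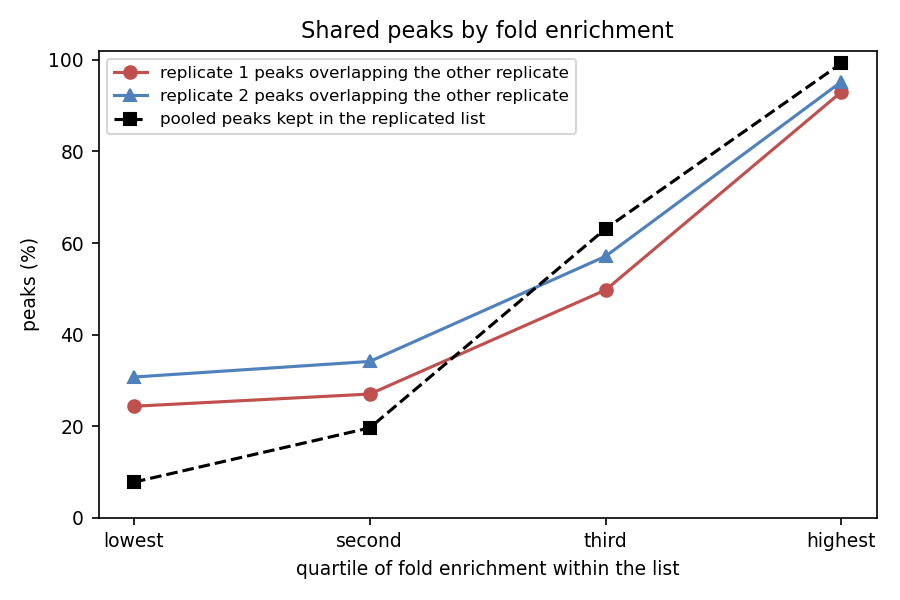
Percent of peaks (vertical axis) by quartile of fold enrichment within each list (horizontal axis) for replicate 1, replicate 2 and the pooled list. In the highest quartile 93.0% and 95.2% of the replicates' peaks were shared, and 99.3% of pooled peaks were kept in the replicated list.

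The replicated list kept 7.80% of the pooled peaks in the lowest quartile of fold enrichment and 99.3% of those in the highest. Of its 55291 peaks, 44978 (81.3%) overlapped a peak in both replicates' own lists, 6176 overlapped one in replicate 1 alone, 3731 one in replicate 2 alone and 406 in neither. With at least 50% of the pooled peak required, 34990 (63.3%) were covered in both lists and 2068 in neither. The median fold enrichment was 4.25 for the 44978 peaks and 3.03 for the other 10313.

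By gene, 12560 protein-coding genes had a promoter peak in replicate 1 and 12382 in replicate 2, and 92.3% of all 21938 genes had the same state in both. A promoter peak was found for 931 genes in replicate 1 alone and for 753 in replicate 2 alone (exact McNemar test, two-sided p = 1.58e-05). Each list comes from 1 pool of embryos, and genes are not independent of each other. The p therefore compares 2 lists of unlike length and does not measure a difference that would recur in other pools. Of 14 endothelial genes 8 had a promoter peak in replicate 1 and 5 in replicate 2, and of 14 skeletal muscle genes 2 and 4 had one. Exact McNemar tests within single lists passed for none, but so few genes differed that no list could have passed the adjusted test alone.

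Replicated peaks lay at gene starts far more often than shifted peaks did. The peak of highest fold enrichment, 65.5, covered the start of Sp3, a transcription factor of many tissues, at chromosome 2, 72978364 to 72981577 (mm10). Next were the start of Arrdc3 at 65.2, an intergenic region of 20984 bases at 62.2 and the start of Nr2f1 at 61.9. The intergenic region lay on chromosome 13 from 83713551 to 83734534, 71.2 kb from the nearest protein-coding start, that of Mef2c, a transcription factor of neurons and muscle. This region overlapped the long noncoding genes C130071C03Rik and Gm26803. The order of the 10 peaks follows the values of the pooled list. In the replicates' own lists the region had 60.0 (rank 4) in replicate 1 and 30.4 (rank 228) in replicate 2. Other peaks among the 10 highest lay within 1 kb of the starts of Rhof (61.7), Kmt5b (60.2), Bicral (59.3) and Dyrk1a (58.9). So did the peak at the pair Gm10762 and Zc3h6 (58.7). The peak near Rhof did not overlap that gene. The last of the 10 (61.0) lay outside protein-coding genes, 15.8 kb from the start of Chd2, and overlapped the long noncoding gene 1810026B05Rik.

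Of the 55291 replicated peaks, 15992 (28.9%) lay within 1 kb of a protein-coding transcription start, against 5.35% ± 0.252 (SD) of shifted peaks. Introns held 35.8% of the peaks against 30.4% of shifted peaks, and intergenic sequence held 29.6% against 58.0%. Each of these 3 differences had p = 0.002 by a two-sided permutation test, the smallest that 1000 shifts can give. Exons held 5.66% against 6.19% (permutation p = 0.0200), a difference that did not pass with a 500-base promoter window (6.35% against 6.68%, permutation p = 0.202). The exon difference turned direction in each replicate's own list (5.99% against 4.80% in replicate 2 and 6.06% against 4.85% in replicate 1). The intron difference turned among peaks at or above the median fold enrichment (26.7% against 28.8%). Peaks at promoters were placed first, so a high promoter share lowers what is left for exons and introns. That share was 28.9% for replicated peaks, 21.8% in replicate 2 and 21.3% in replicate 1. Among peaks at or above the median fold enrichment it was 42.6%. The lower exon and intron shares therefore do not show that peaks avoid these places.

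Gene lists fixed beforehand were used to ask which cell types and brain regions had acetylated promoters. Every gene of the telencephalon lists carried a promoter peak in the replicated list: 18 of 18 dorsal genes (adjusted p = 8.15e-05) and 20 of 20 ventral genes (adjusted p = 3.04e-05), by Fisher's exact test against all other protein-coding genes, of which 53.4% had one. The dorsal genes with the most covered bases in their territory were Nr2f1 (44.2 kb, promoter fold enrichment 61.9), Bcl11b (39.4 kb, 30.2), Lhx2 (30.9 kb, 20.0) and Pax6 (26.6 kb, 20.8), all transcription factors of cortical development. The ventral genes with the most were Meis2 (44.4 kb, 26.8), Six3 (20.1 kb, 18.7), Arx (19.4 kb, 8.95) and Dlx6 (19.3 kb, 20.9), transcription factors of the ventral forebrain and its GABAergic neurons. Mean covered sequence was 16.2 kb ± 11.9 per dorsal gene (SD, n = 18 genes) and 13.0 kb ± 9.22 per ventral gene (SD, n = 20 genes), and 1.92 kb ± 4.45 over all protein-coding genes.

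Genes of neural progenitors and of newborn neurons were covered as fully. All 16 progenitor genes had a promoter peak (Fisher's exact test, adjusted p = 1.67e-04), led by Sox2 with 45.5 kb, Notch1, the receptor that holds progenitors undifferentiated, with 41.3 kb, Msi1 with 32.2 kb and Sox1 with 30.8 kb. All 17 newborn neuron genes had one (Fisher's exact test, adjusted p = 1.23e-04), led by the RNA-binding proteins Celf4 (49.1 kb) and Rbfox3 (36.6 kb), the transcription factor Myt1l (32.9 kb) and the microtubule protein Map2 (15.3 kb). The median promoter fold enrichment was 18.9 over the progenitor genes, 14.8 over the dorsal genes, 12.4 over the newborn neuron genes and 10.2 over the ventral genes, against 9.05 over all genes with a promoter peak and 19.3 over the housekeeping genes.

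Of the genes common to most cells, 15 of 15 housekeeping genes had a promoter peak (Fisher's exact test, adjusted p = 2.78e-04), with the most covered sequence at Eef1a1 (13.1 kb), Actb (9.19 kb), Gapdh (6.41 kb) and Ubc (6.08 kb). Of the cell cycle genes 14 of 16 had one (Fisher's exact test, adjusted p = 0.0102), with Rrm2 (3.82 kb), Aurkb (2.75 kb), Mcm2 (2.40 kb) and Mki67 (1.99 kb) covered most and Mcm3 and Bub1 without one. Of the patterning signals 14 of 17 had one (Fisher's exact test, adjusted p = 0.0423), led by the Hedgehog pathway genes Gli2 (29.4 kb), Ptch1 (26.9 kb) and Gli3 (25.7 kb) and by Wnt7b (25.6 kb). The patterning genes without one were Fgf8, Fgf17 and Bmp4, ligands made in small signalling centres; Fgf17 and Bmp4 had one in replicate 1 and in the pooled list.

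Promoters of the midbrain, hindbrain and trunk were largely without peaks. None of the 39 Hox genes, which set position from the hindbrain to the tail, had a promoter peak in the replicated list (Fisher's exact test, adjusted p = 1.31e-12). Of 18 midbrain and hindbrain genes, 3 of which are also Hox genes, only Mafb, a factor of hindbrain segments and of macrophages, had one, with a fold enrichment of 8.61 (Fisher's exact test, adjusted p = 1.41e-04). In each replicate's own list 4 of these 18 genes and 1 of the 39 Hox genes had one. Pax7 and Pax2, factors of the midbrain, had no promoter peak in the replicated list but 10 and 4 distal peaks, and Pax7 had a promoter peak in each replicate's own list. Of 1135 olfactory receptor genes, expressed in the nose, only Olfr452 and Olfr1391 had a promoter peak in the replicated list, against 56.3% of other genes. In the own lists of replicates 1 and 2, 6 and 2 olfactory receptor genes had one, and 0 had one in both.

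Genes of the skeletal muscle, liver, heart, microglia, eye and endothelial lists had promoter peaks less often than other genes in the replicated list, and those of the limb mesenchyme list did not pass the test. The counts were 1 of 14 for skeletal muscle (Myh3; Fisher's exact test, adjusted p = 0.00143), 2 of 16 for liver (Afp and Foxa3; exact adjusted p = 0.00365) and 3 of 17 for heart (Nppa, Myh7 and Ryr2; exact adjusted p = 0.00689). They were 2 of 14 for microglia and macrophages (Tmem119 and Csf1r; Fisher's exact test, adjusted p = 0.0102), 3 of 14 for eye (Rlbp1, Pmel and Atoh7) and 3 of 14 for endothelium (Pecam1, Mfsd2a and Egfl7), both with exact adjusted p = 0.0423. Their promoter peaks had fold enrichments such as 3.31 at Pecam1, 3.49 at Afp, 7.90 at the retinal gene Rlbp1 and 10.99 at the cardiac myosin gene Myh7. The endothelial call was lost in the lists of replicate 2 (5 of 14 genes, exact adjusted p = 0.222), replicate 1 (8 of 14, 1) and the pooled peaks (7 of 14, 0.674), and the microglial call in those of replicate 1 and the pooled peaks (5 of 14 each, 0.143 and 0.129). The skeletal muscle, eye and patterning calls were lost in replicate 2 alone (exact adjusted p = 0.0831 each), the eye call also with an overlap of 500 bases (0.0803) and with 1 start per gene (0.0766), the patterning call without olfactory receptor genes in the background (0.0664), the heart call with a 2.5 kb window (0.0643) and the cell cycle call with an overlap of 500 bases (0.0553).

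**Figure D2:**
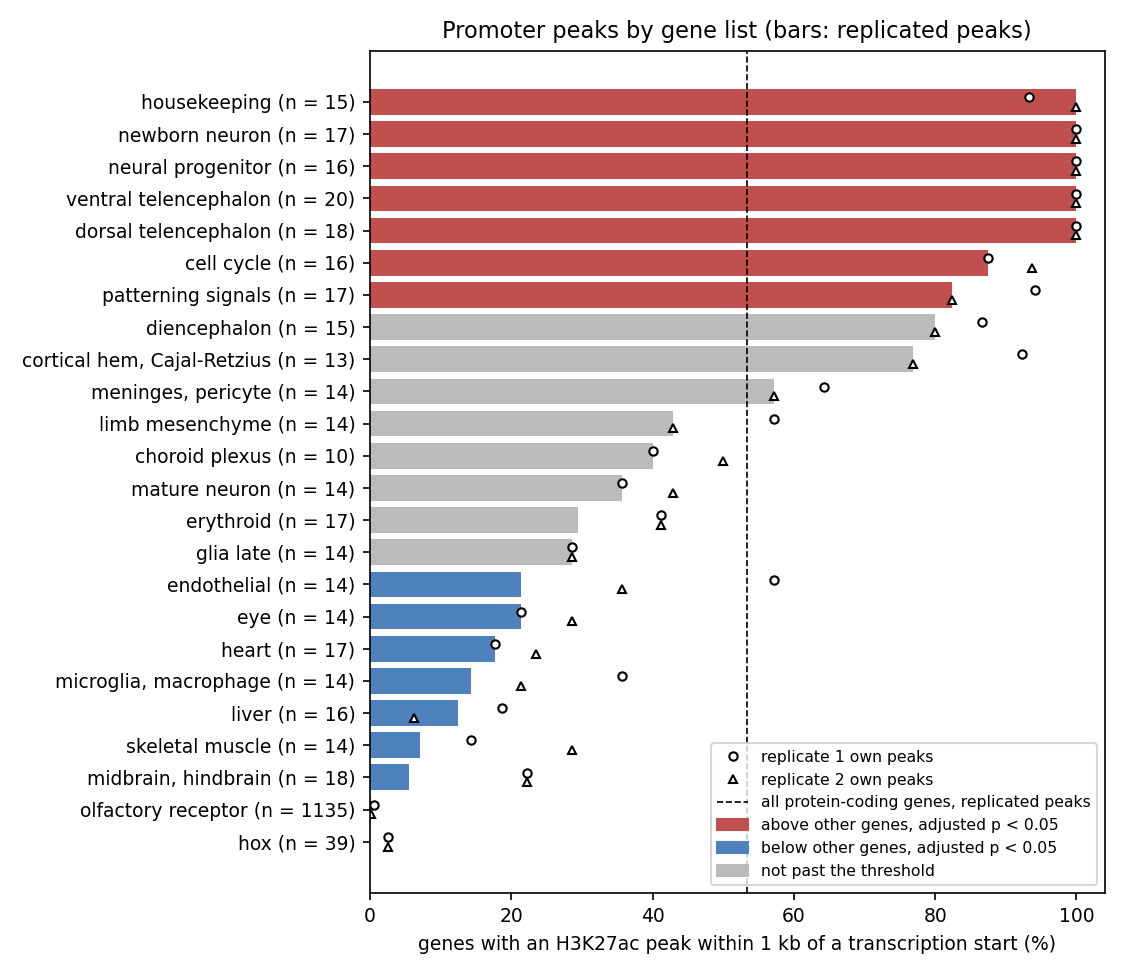
Percent of the genes of each list with a promoter peak (horizontal axis), with bars for the replicated list and symbols for each replicate's own list. The dashed line marks the 53.4% of all protein-coding genes; the 4 lists of telencephalon, progenitor and newborn neuron genes reach 100% and the 39 Hox genes stand at 0 in the replicated list.

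The 8 other lists did not pass the test. In the diencephalon list 12 of 15 genes had a promoter peak (Fisher's exact test, adjusted p = 0.0883), with Tcf7l2, a thalamic transcription factor, covered by 32.1 kb, Otx2 by 18.7 kb, Barhl2 by 17.1 kb and Vax1 by 13.4 kb, and Rax, Six6 and Sim2 without one. In the list of the cortical hem and Cajal-Retzius cells 10 of 13 had one (exact adjusted p = 0.125), with Lhx5 (20.95 kb), Ebf3 (12.4 kb), Wnt8b (9.005 kb) and Rspo1 (7.68 kb) covered most and Wnt2b, Calb2 and Trp73 without one. Meninges and pericyte genes had 8 of 14 (exact adjusted p = 1), with the most covered sequence at Pdgfrb (5.11 kb), Col1a1 (4.97 kb), Foxc1 (4.94 kb) and Foxd1 (3.63 kb). Limb mesenchyme genes had 6 of 14 (exact adjusted p = 0.478), with Prrx2 (6.33 kb), Prrx1 (5.68 kb), Lmx1b (5.41 kb) and Alx4 (4.01 kb) covered most. The choroid plexus list had 4 of 10 (Otx2, Foxj1, Lmx1a and Folr1; exact adjusted p = 0.553). Late glial genes had 4 of 14 (Slc1a2, Mbp, Sox10 and Mobp; exact adjusted p = 0.125), mature neuron genes 5 of 14 (Camk2a, Kcnc1, Slc17a7, Arc and Bdnf; exact adjusted p = 0.324) and erythroid genes 5 of 17 (Nfe2, Ank1, Tal1, Klf1 and Gypa; exact adjusted p = 0.0756). Under some alternatives 4 of these lists passed, the diencephalon (lowest exact adjusted p = 0.0236) and cortical hem lists (0.0187) above other genes and the late glial (0.00338) and erythroid lists (7.76e-05) below them.

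Tested directly against each other, telencephalon genes and genes of other regions differed. All 38 dorsal and ventral telencephalon genes had a promoter peak, against 1 of 18 midbrain and hindbrain genes (Fisher's exact test, two-sided p = 1.84e-13) and 12 of 60 genes of heart, liver, limb and skeletal muscle (Fisher's exact test, p = 5.91e-17). Telencephalon genes had 8.58 ± 8.32 distal peaks each (SD, n = 38 genes), midbrain and hindbrain genes 1.17 ± 2.46 (n = 18 genes, permutation test, p = 3.3e-04) and genes of the other organs 0.900 ± 1.71 (n = 60 genes, permutation test, p = 1e-05, the smallest that 100000 resamples can give). Among peaks at or above the median fold enrichment 5 of the 60 genes of other organs had a promoter peak (Fisher's exact test, p = 2.2e-20). In the longer lists of replicates 1 and 2 telencephalon genes had 14.2 and 14.7 distal peaks each and midbrain and hindbrain genes 2.28 and 3.17 (permutation test, p = 3.8e-04 and 7e-04). At Emx2, a dorsal telencephalon factor on chromosome 19, 6 replicated peaks covered 18.1 kb, and both replicates' own lists covered the same interval. The interval of the Hoxa genes on chromosome 6 held no replicated and no pooled peak, 1 peak of replicate 1 and 2 peaks of replicate 2.

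**Figure D3:**
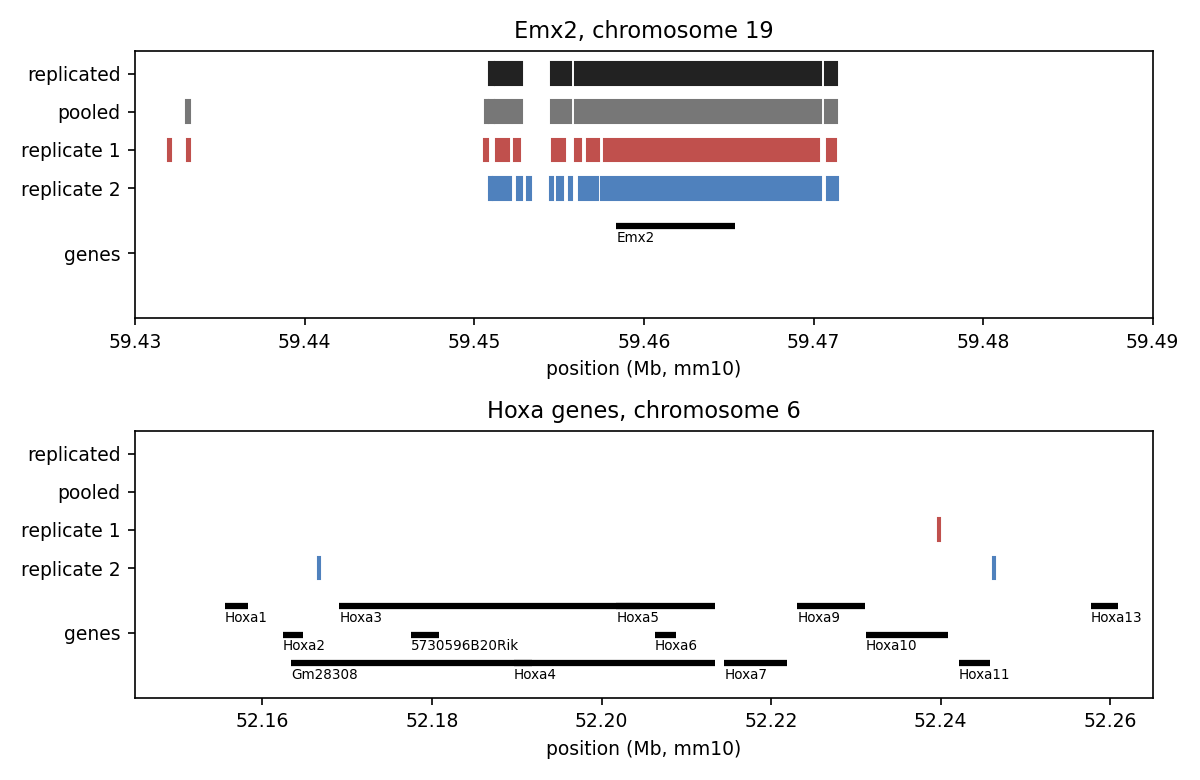
Peaks of each list (boxes) and protein-coding genes (black lines) along mm10 positions in Mb around Emx2 on chromosome 19 and across the Hoxa genes on chromosome 6. Emx2 is covered by peaks in all 4 lists, and the Hoxa interval holds 1 peak of replicate 1, 2 of replicate 2 and none of the other lists.

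Away from promoters, the genes with the most distal replicated peaks were Msi2 (100 peaks), an RNA-binding protein of progenitors, Gse1 (95), Zmiz1 (82), a transcriptional coactivator, Bach2 (69) and Ephb2 (63), a receptor of axon guidance. They were followed by Zfp423 (61), Auts2 (60), Tenm4 (55), Tcf4 (54) and, tied, Prdm16, Pbx1 and Foxn3 (53 each). Of all replicated peaks 39299 (71.1%) were distal, and 31839 of these lay within 100 kb of the nearest protein-coding start. The mean was 1.45 per gene, 2.30 for genes with a promoter peak and 0.472 for genes without one, and 7394 genes had any.

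Telencephalon, progenitor and newborn neuron genes had more distal peaks than random lists matched on territory length. Dorsal telencephalon genes had 8.33 ± 8.42 each (SD, n = 18 genes) against 2.02 in matched lists (permutation test, adjusted p = 0.00360), and ventral genes had 8.80 ± 8.45 (SD, n = 20 genes) against 2.47 (permutation test, adjusted p = 0.00704). Every gene of both lists had at least 1, with 38 at Meis2, 37 at Bcl11b and 16 at Nr2f1. Progenitor genes had 10.2 ± 8.02 against 3.11 (n = 16 genes, permutation test, adjusted p = 0.0187), with 21 at Sox2 and 19 at Msi1. Newborn neuron genes had 9.71 ± 13.4 against 3.28 (n = 17 genes, permutation test, adjusted p = 0.0257), with 43 at Rbfox3 and 39 at Celf4.

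Olfactory receptor genes had 0.0176 ± 0.182 against 0.449 (n = 1135 genes, permutation test, adjusted p = 4.8e-04), and none of the 16 liver genes had a distal peak, against 1.04 in matched lists (permutation test, adjusted p = 0.0257). The other 18 lists did not pass. They included the patterning signals (6.71 against 2.61, permutation test, adjusted p = 0.0752), with 21 at both Gli2 and Gli3, the diencephalon genes (6.27 against 2.56, permutation test, adjusted p = 0.101), with 32 at Tcf7l2, and the Hox genes (0.0769 against 0.368, permutation test, adjusted p = 0.118), of which only Hoxa1 had any, with 3. The Hox genes stood below matched lists in the lists of replicate 1, replicate 2 and the pooled peaks (permutation adjusted p = 0.0217, 0.0334 and 0.0136), the patterning signals above them in replicate 1 and the pooled peaks (0.0373 and 0.0313), and the diencephalon genes above them with a 50 kb limit (0.0322). The newborn neuron call was lost at −log10 q of at least 5, with a 50 kb limit and against genes with a promoter peak only (permutation adjusted p = 0.0540, 0.0676 and 0.233). The liver call was lost in replicate 2 alone (0.562 per gene, permutation adjusted p = 0.158) and in 5 other settings (permutation adjusted p = 0.0506 to 0.240). Against genes with a promoter peak only, 2 liver and 2 olfactory receptor genes were left, and neither list passed (permutation adjusted p = 0.944 for liver). So few genes cannot decide the question.

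**Figure D4:**
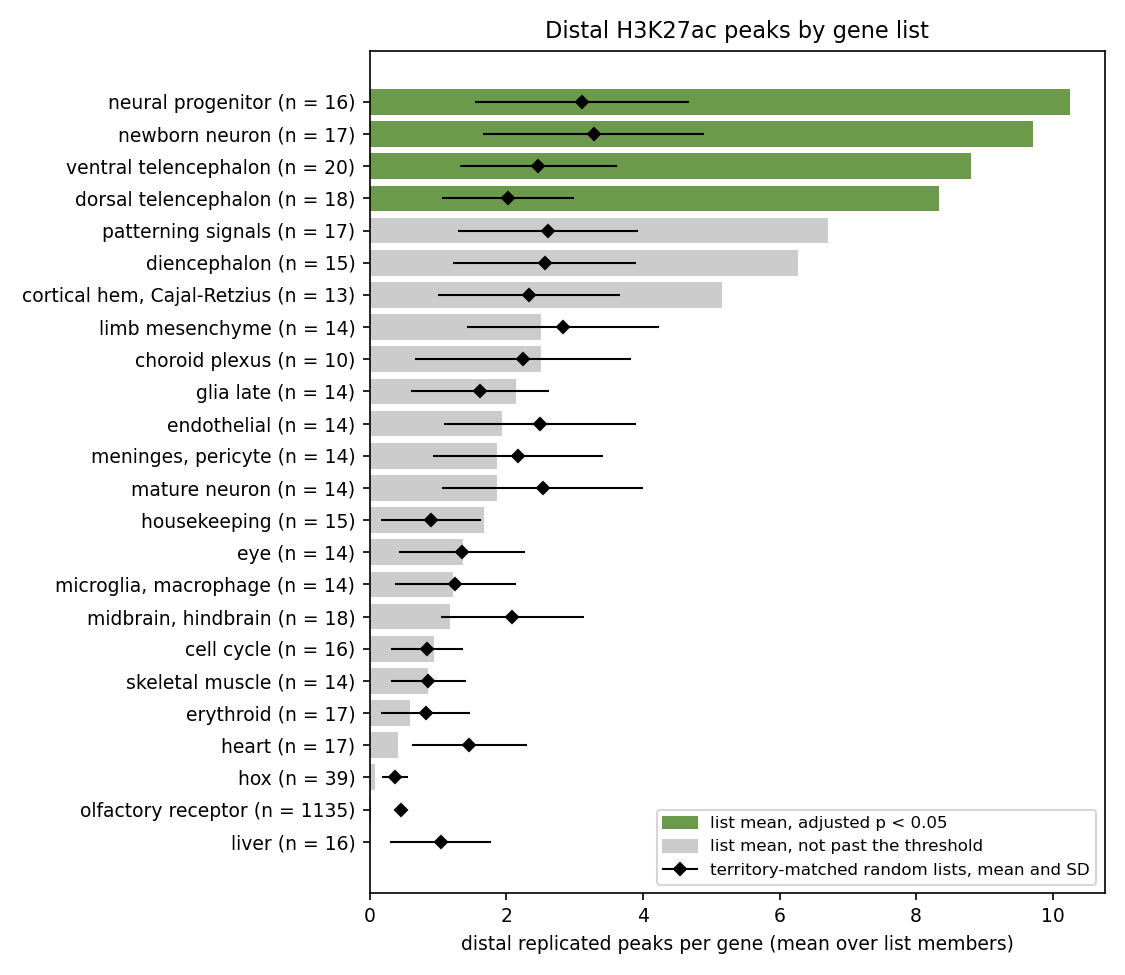
Mean number of distal replicated peaks per gene (horizontal axis) for each list (bars), with the mean and SD of matched random lists (diamonds and lines). Progenitor, newborn neuron, ventral and dorsal telencephalon genes reach 10.2, 9.71, 8.80 and 8.33, above matched lists at 3.11, 3.28, 2.47 and 2.02.

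Peaks lying within 12.5 kb of each other were stitched to describe clustered acetylation. The domain with the most covered sequence had 172 kb at Gse1 and Gins2 on chromosome 8, from 120249714 to 120603258, and the next had 168 kb at Msi2 on chromosome 11, from 88372975 to 88729816. Domains of 88.7 kb at 1700001O22Rik and Ntmt1, 87.3 kb at Zmiz1, 74.3 kb at Irf2bpl and Cipc and 71.1 kb at Rhcg followed. The domains ranked 7 to 10 lay at Src, Blcap and Nnat (67.5 kb), at the nuclear corepressor Ncor2 (66.3 kb), at Cxxc5 and Psd2 (63.2 kb) and over 12 genes from Sbno2 to Dazap1 (57.1 kb). Those ranked 11 to 20 lay at Pbx1, Rapgef5, Trak1, Ephb2, Prdm16, Rhbg, Myo18a with Pipox and Sez6, Bahcc1, Igdcc4 with Igdcc3 and Parp16, and Ccdc33 with Stra6, and covered 55.6 to 47.2 kb. Of the 500 highest domains 421 held a protein-coding start, and the others are named by the nearest one, which need not be the gene concerned. The widest replicated peak, over Mir9-1, overlapped no protein-coding gene, and its nearest protein-coding start was that of Rhbg, 36.5 kb away.

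The 500 highest-ranked of 22779 domains held 22.0% of the covered bases and were assigned to 937 genes. Dorsal telencephalon genes were among them 11 times in 18 (Fisher's exact test, adjusted p = 2.36e-10), progenitor genes 9 times in 16 (exact adjusted p = 3.18e-08), ventral telencephalon genes 8 times in 20 (exact adjusted p = 5.14e-06) and patterning signals 4 times in 17 (exact adjusted p = 0.0242). Of the newborn neuron genes 3 of 17 were among them (Fisher's exact test, adjusted p = 0.135), and of the 1135 olfactory receptor genes none was (exact adjusted p = 3.59e-21). The other 18 lists had at most 2 members there and did not pass. Housekeeping genes, with 2 of 15, had 4 of 15 in the list of each replicate (exact adjusted p = 0.0343 and 0.0346) and in the pooled list (0.0414), 5 when domains were ranked by fold enrichment times length (0.00169) and 6 with 1000 domains (0.00248). Diencephalon genes passed with stitching at 3 kb (exact adjusted p = 8.93e-05) and newborn neuron genes without stitching (5.26e-05). The patterning call was lost with peaks at −log10 q of at least 5 (3 genes, exact adjusted p = 0.103), with ranking by fold enrichment times length (3 genes, 0.149) and with 250 domains (2 genes, 0.182), and with 1000 domains 8 lists in place of 4 stood above other genes.

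**Figure D5:**
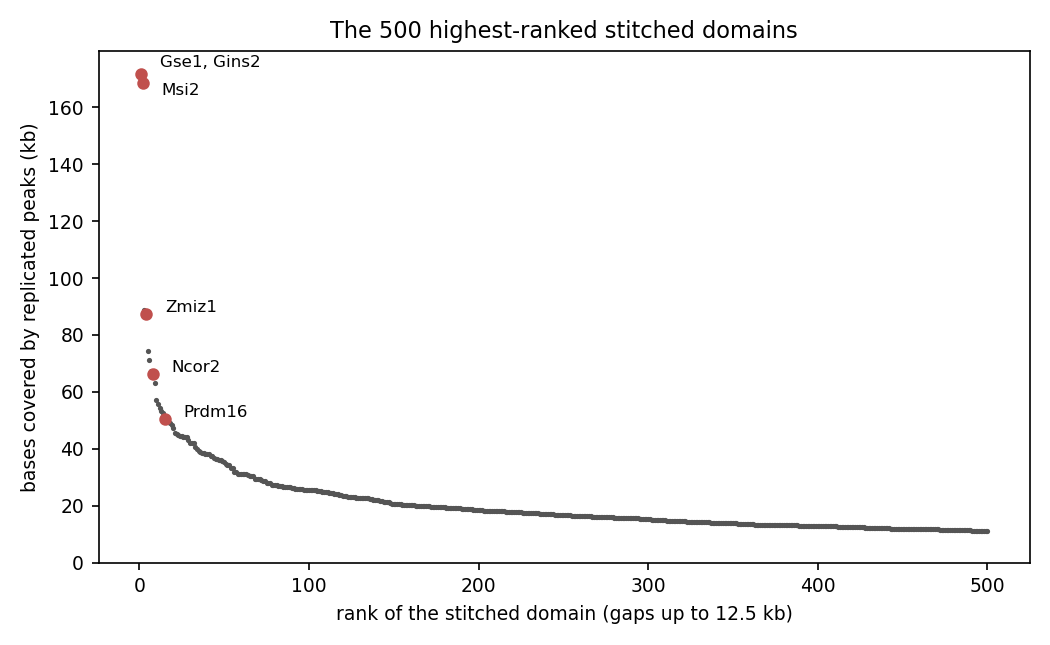
Bases covered by replicated peaks in kb (vertical axis) for the 500 highest-ranked stitched domains (points, by rank on the horizontal axis). The domains at Gse1 with Gins2 and at Msi2 cover 172 and 168 kb, and Zmiz1, Ncor2 and Prdm16 are named at 87.3, 66.3 and 50.5 kb.

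Binding motifs of transcription factors were searched in 30271 distal peaks, and none of the 17 motifs passed the adjusted test. The motif of SOX factors ACAAAG was 1.19 times as frequent per kb in peaks as beside them and had the highest ratio of its 25 rearrangements (exact rank test, one-sided p = 0.04, adjusted p = 0.227). The proneural E-box CAGCTG had a ratio of 1.79 and the highest rank of 42 (exact rank test, p = 0.0238, adjusted p = 0.202); it ranked 2 or 4 in every alternative (exact p = 0.0476 or 0.0952). The POU motif ATTTGCA had a ratio of 1.13 and rank 8 of 360 (exact rank test, p = 0.0222, adjusted p = 0.202). These were the 3 motifs at an unadjusted p under 0.05. Other motifs of the same families did not stand out. The SOX motif ACAATG had a ratio of 0.971 and rank 20 of 100 (exact rank test, p = 0.2). The proneural E-box CAGATG had a ratio of 1.12 and rank 26 of 120 (exact rank test, p = 0.217). The homeodomain motif TAATTA had a ratio of 1.00 and the highest of its 14 ranks, against a median of 0.593 over the rearrangements. It kept that rank in every alternative, with ratios from 0.639 (200 bases around the summit) to 0.968 (control 5 kb to the left). The exact rank test cannot give a p under 0.0714 for TAATTA, 0.04 for ACAAAG or 0.0238 for CAGCTG, and of the 17 motifs only ATTTGCA and TGACTCA had enough rearrangements to pass the adjusted test alone. The liver factor motif CAAAGTC had rank 140 of 300 (exact rank test, p = 0.467). Base composition differed, with 49.4% G and C in peaks and 44.7% beside them.

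Chromosome X held fewer peaks than the autosomes. There were 5.26 replicated peaks per Mb on X and 22.1 per Mb on the 19 autosomes, a ratio of 0.238 (95% interval 0.223 to 0.254, counting error only). Among autosomes the density ran from 15.5 per Mb on chromosome 3 to 35.5 per Mb on chromosome 11. Of 948 protein-coding genes on X, 334 (35.2%) had a promoter peak, against 54.7% of autosomal genes (Fisher's exact test, two-sided p = 4.46e-32). Arx, an interneuron factor on X, had 9 distal peaks and a promoter peak in both replicates. Distal peaks on X were 0.171 times as dense per Mb as on autosomes, and promoter peaks per gene were at 0.617 of the autosomal value.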

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

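The alternative that keeps only replicated peaks found in both replicates' own lists was chosen after seeing the data; all others were fixed before the data were examined. Over the main results, 110 of 122 alternatives were counted as the same. For tests this meant the same direction and side of the threshold, and for counts a value within 1.5 times the reported count. The 12 others include values without a test, Spearman's rho and the X-to-autosome ratio, which moved but kept their direction. Shares of pooled peaks kept by quartile could not change with the overlap required, because every replicated peak is an identical pooled entry. Spearman's rho of matched fold enrichments was 0.803 among peaks at or above the median fold enrichment and 0.812 at −log10 q of at least 5, against 0.724. The exon share reversed against chance in the replicates' own lists (5.99 to 6.06%) and in the pooled list (6.57%) and did not pass with a 500-base promoter window (6.35%), and the intron share reversed at or above the median fold enrichment (26.7%). The number of lists with fewer distal peaks than matched lists was 1 in place of 2 for peaks at or above the median fold enrichment, for −log10 q of at least 5, for peaks in both replicates' lists, for a 2.5 kb window and for a 500 kb limit, and 0 against genes with a promoter peak, where 2 liver and 2 olfactory receptor genes were left, too few to pass. With 1000 domains, 8 lists stood above other genes in place of 4. The X-to-autosome ratio of peaks per Mb was 0.186 in both replicates' own lists and 0.166 in the pooled list, against 0.238. The exon and intron shares also depend on the promoter share, since peaks at promoters were placed first. The cause of the changes above was not tested.

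Over single lists, 234 of 264 promoter, 244 of 261 distal and 251 of 264 domain alternatives gave the same call; 13, 11 and 3 lost a call and 17, 6 and 10 gained one, and none reversed. Calls were gained for promoter peaks by the diencephalon, cortical hem, late glial and erythroid lists, for distal peaks by the Hox, patterning and diencephalon lists, and for domains by the housekeeping, diencephalon, newborn neuron and cortical hem lists. The comparisons of telencephalon genes with other regions and tissues kept their direction and call in every alternative run. No motif passed in any, which for most motifs says nothing about stability, since their rearrangements are too few to pass alone. No paired analysis was possible because the series has 1 group. Depth is unknown, so whether weak peaks found in 1 replicate only reflect fewer reads could not be tested.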

Other observations

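The tests of globin and other erythroid genes, of repeats in peaks of like width and of raised fold enrichments on chromosome X were chosen only after the results were seen; the regions, genes and microRNAs below were also chosen after their values were seen, and the other tests were written down before their outcomes. Of the replicated peaks, as distinct from stitched domains, those ranked 1, 2 and 4 by width lay over genes that make no protein. The widest, 43558 bases on chromosome 3 from 88196427 to 88239984, covered Mir9-1, and the next, 43174 bases on chromosome 7 from 79495675 to 79538848, covered Mir9-3 and its host transcript Mir9-3hg. The peak at rank 4, 20984 bases on chromosome 13, covered the long noncoding gene C130071C03Rik, and Mir9-2 lay in a separate peak of 5012 bases beside it. The others among the 7 widest had 23637 bases at Notch1 (rank 3), 15427 bases at Sox2 and Sox2ot, 15188 bases at Msi1 and 14499 bases at Emx2 and Emx2os. Mir124a-1 and Mir124a-3, microRNA genes of neurons, lay in peaks of 11514 and 9690 bases, ranked 16 and 29 by width.

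Distal peaks of high fold enrichment outside the stitched domains already named included 1 on chromosome 12 from 49399639 to 49402251 (fold enrichment 47.4), downstream of the telencephalon factor Foxg1 (49382660 to 49386861) and 15.8 kb from the nearest protein-coding start, that of Gm43517, and 1 on chromosome 6 from 134926523 to 134929621 (40.5), 7.56 kb from the start of Cdkn1b, an inhibitor of the cell cycle. Over the 71 genes of the telencephalon, progenitor and newborn neuron lists the median fold enrichment at the promoter was 13.7, and over the 30 genes of 8 non-neural lists that had a peak it was 3.49, a difference that was not tested. Other neural lists lay lower, with 6.52 for the diencephalon, 6.22 for mature neurons, 4.40 for the cortical hem and Cajal-Retzius cells and 3.55 for late glia, and the limb mesenchyme list stood at 5.51.

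Chromosome X had 0.238 times the autosomal number of peaks per Mb; no biological explanation, such as inactivation of 1 X in females, was tested, because the pools hold both sexes. A low number of genes on X, as the whole cause, is argued against by the ratio per protein-coding gene, 0.363 (95% interval 0.339 to 0.388). Repeat content is argued against in the same way by the ratio per Mb outside repeats, 0.303 (0.283 to 0.323), though gene number and repeats could each explain a part and were not combined. Lower detection at the 1 copy of X in males stays open: within the quartile of highest fold enrichment the ratio was 0.364 (0.326 to 0.405), under the bound of 0.8 set for it, but that bound holds only if the control cancels copy number in the fold enrichment, which the sources do not tell. If it does not, X peaks with their fold enrichment multiplied by 2, the most that 1 copy in place of 2 could take, reach 0.868 (0.808 to 0.932), and 0.505 if multiplied for as many males as females, whose shares are unknown.

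All 3 microRNA-9 genes lay in peaks among the 266 widest. Each replicate's own peaks together covered at least 97.7% of each of the 3 peaks. That argues against pooling of the replicates as the source of the acetylated extent, but not of the width of single peaks. The widest peak of replicate 2 had 31715 bases, so the peaks at Mir9-1 and Mir9-3 (43558 and 43174 bases) were wider than any single peak there. Reads piled up on repeats stay possible by a first test, in which the repeat-masked shares (13.3 to 16.3%) lay above the median of distal peaks, 9.57%, while among the 300 widest other peaks the shares stood at most at percentile 72.7, below the percentile of 90 set for that explanation. A hypothesis that goes with the data is that microRNA genes of the nervous system tend to lie in acetylated chromatin at this stage: 9 of 12 neural microRNA genes other than microRNA-9 had a peak within 1 kb, against 2 of 15 of muscle, liver and blood (Fisher's exact test, two-sided p = 0.00195) and 17.2% of all 2202 microRNA genes. That test bears on acetylation, not on width, and peaks of neighbouring genes were not set apart in it. It also counts clustered genes as independent, so its p may be too small. Mir1a-1 and Mir133a-2, Mir1a-2 and Mir133a-1, and Mir144 and Mir451a each lie close together and share their nearest peak.

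Of 119 genes in 8 non-neural lists, 30 (25.2%) had a promoter peak, against 53.4% of all protein-coding genes. Placement of peaks without regard to genes is argued against by circular shifts (mean 10.6, highest 22, permutation test, one-sided p = 0.001, the smallest possible). Shifts also remove the preference of all peaks for promoters, so they show no excess of these genes over other genes. Sharing the promoter of a neighbouring gene is argued against as the main cause, since 6.67% of the 30 did so (Egfl7 and Foxa3). Red blood cells could not be decided: 0 of the 7 globin genes had a replicated promoter peak, but reads of the near-identical copies Hba-a1 and Hba-a2, and Hbb-bt and Hbb-bs, could have been lost in mapping, and 5 of the 10 other erythroid genes had one, against 24.5% of the genes of the other 7 lists. Mesenchymal cells in the tissue, such as those of the meninges, remain a candidate source that could not be decided: 41.7% of 12 fibroblast matrix genes had a promoter peak (Col5a1, Col5a2, Fbn1, Fbln1 and Mfap4; exact 95% interval 15.2 to 72.3%), against 57.1% of the meninges and pericyte list, with Col1a2 at a fold enrichment of 3.36 and Col3a1 at 3.34. Some of the 30, such as Tal1, Foxd1, Msx1, Ryr2 and Ank1, are also known from brain cells, and acetylation by the forebrain's own cells was not tested.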
